A study of Arabidopsis thaliana with 12 samples.

How the data were processed

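RNA was sequenced from leaf and root of Arabidopsis thaliana Col seedlings aged 10 days, grown without particles or with PS-SO3H or PS-NH2 nanoplastics at 50 ug/ml, with 2 libraries for each of 6 groups. Total RNA was taken with Trizol and reverse transcribed with random primers, per the labels' protocols. Genome build TAIR10 is named in the submitters' processing notes. The series text names the aligner SOAP2 and a test without replicates, but it also describes a size-selected small RNA library, so it is unclear which of its steps apply to these tables. The counting program, its treatment of multi-mapping reads and its version are not given in the sources used here.

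Each of the 4 deposited tables sets 1 particle against control in 1 tissue and was made by the authors with a DESeq2 method, per the labels of the deposited tables. The deposited level of each group is a signal on the scale of reads divided by size factors, not divided by gene length, and the authors fitted it together with the fold change. The same control libraries therefore have different levels in the 2 tables of a tissue, close for most genes and far apart for some, among them PR1 in leaf. Over genes in both tables the log2 ratio of the 2 control levels departed from its median by 0.00263 in leaf and 0.00196 in root (median absolute deviation), and by up to 1.07 and 0.618. The deposited log2 fold change is treated over control and is small for low genes, as a shrunken estimate is. It matched the log2 ratio of the level columns to within 4.87e-08. The deposited p-value and adjusted p come from the authors. The adjusted p was recomputed by the Benjamini-Hochberg method and differed by more than 1e-06 in 96 genes of the leaf PS-SO3H table, which prints rounded values, and in 0 genes of the other tables. The tables give no value per library, so read depth per library is unknown and no test across libraries was run here. A design based on counts per library had been written before the data were examined, with the branch used here as its stated substitute.

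A gene was called changed where the authors' adjusted p was below 0.05. The authors' up and down marks were found to require in addition an absolute log2 fold change of at least 1. The SE of a fold change was recovered as its size divided by the normal quantile of the authors' p-value, and had a median of 0.208 and 0.220 in leaf (PS-SO3H and PS-NH2) and 0.165 and 0.163 in root. At levels of 200 or more the medians were 0.169, 0.162, 0.130 and 0.130. The 95% intervals rest on this SE. Particle and tissue differences were computed per gene as the difference of 2 log2 fold changes, with the squared SEs added, a 2-sided normal p and Benjamini-Hochberg adjustment. Particles share control libraries, so that SE is too large for the particle difference. Cross-table differences rest on tables normalized separately by the authors.

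In total, 24 gene lists with 447 members were fixed before the data were examined: salicylic acid, jasmonate, ethylene, antioxidant enzymes, reactive oxygen, glutathione S-transferases, early immunity, glucosinolates, flavonoids, cold and drought, heat shock, iron, phosphate, sulfur, nitrogen, auxin, cell wall loosening, cell cycle, aquaporins, photosynthesis, root hair, root cell types, seed storage and clock. Photosynthesis served also as a marker of green tissue in root, root cell types as a marker of root in leaf, seed storage as a marker of seed tissue and clock as a marker of harvest time. Each list was tested per direction with a one-sided Fisher's exact test of called members against all genes of the table, adjusted over 48 tests per comparison. Genes of a list are not independent, so these p-values may be far too small, and they measure no spread between libraries. The other genes were not matched for level, and 3724 to 4201 genes per comparison with control had a mean level below 10. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members' p-values. Each list median was also ranked among 10000 random lists matched on mean level in 10 bins.

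Genes named in the text follow a rule fixed before the data were examined: the 8 highest and 8 lowest called genes per comparison with a symbol and a mean level of at least 50, the 5 highest and 5 lowest per difference, up to 4 called members per list in order of list p until about 20 were named, and 12 fixed genes. Not every gene so chosen is discussed, and the result of 1 is not reported here. Other list members are named where few members changed or as examples, and these were chosen after their values were seen. Loci were matched to the TAIR10.1 reference for symbols, with 24708 of 24912 loci found. No coordinates are given, because the reference build differs from the one the submitters name. The leaf PS-SO3H table holds 22 symbols turned into dates, so loci were used throughout. GR2 kept the locus fixed in advance (AT3G54660), although the reference gives that symbol to another locus. Genes with near-identical copies (LHCB1.1, LHCB1.2 and LHCB1.3; RBCS1B, RBCS2B and RBCS3B; PDF1.2A and PDF1.2C; VSP1 and VSP2; KIN1 and KIN2; COR15A and COR15B; PP2-B13 and PP2-B14) are uncertain, since the counting could split their reads.

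The overlap counts of both particles were set beside n1 x n2 / N, and their correlation and covariance beside 100 simulated draws of unchanged groups against shared controls. The difference test was tested on simulated data with 200 changed genes. At a log2 difference of 1 and 2 it recovered 56.7% and 97.1% for the particles in leaf, 63.7% and 100% for the particles in root, 54.5% and 98.0% between tissues with PS-SO3H, and 58.8% and 98.0% with PS-NH2. False calls were 0%, 0%, 4.97% and 0.637% of all calls. These draws took normal errors from the recovered SE that the test then used, so few false calls follow by construction. Changes were planted only in genes with a mean level of at least 50. How the test behaves with a wrong SE, with shrunken fold changes or for low genes was not measured. The list test called the 1 planted list and 0 of 200 random lists. That simulation took only the genes listed in the leaf PS-NH2 comparison, with calls and random lists drawn at random. It does not show how often lists of genes that move together are called falsely. Alternatives were other thresholds, an expression floor of 10 or 200, recomputed adjustment, re-centring, both directions together, a covariance for shared controls, and other pseudocounts (1 in the tissue check) or scalings. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.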

Results

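Messenger RNA levels were compared in leaf and root of 10-day-old wild-type Arabidopsis thaliana seedlings (Col) raised on MS medium. Seedlings grew without particles or with polystyrene nanoplastics at 50 ug/ml, bearing sulfonic acid groups (PS-SO3H) or amino groups (PS-NH2) as their names give them. The 6 groups of tissue and treatment held 2 libraries each, 12 in all. The authors deposited 4 comparison tables, each setting 1 particle against control in 1 tissue. A table gives a fitted level per group, a log2 fold change, a p-value and an adjusted p per gene, and no value per library. These are fitted levels, not read totals, so the depth of each library is unknown. Levels, log2 fold changes and adjusted p-values given for single genes against control are those of the authors' deposited tables. The standard error (SE) beside a fold change was recovered from the authors' fold change and p-value. The p-values rest on the spread between libraries as the authors' method modelled it. Without values per library, a small p does not show that the 2 libraries of a group agree for that gene. Nothing in the labels says that those 2 libraries came from separate plants or cultures.

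Tissue labels were checked with marker lists on the control levels of the authors' deposited tables. The 34 photosynthesis genes were higher in leaf, with a median log2 ratio of root over leaf of -6.02. The 18 root hair genes were higher in root with a median of 6.38, and so were the 11 genes of root cell types, with a median of 5.56. Under median or upper-quartile scaling, 10 of those 11 were higher in root. The leaf and root tables were normalized separately.

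**Figure D1:**
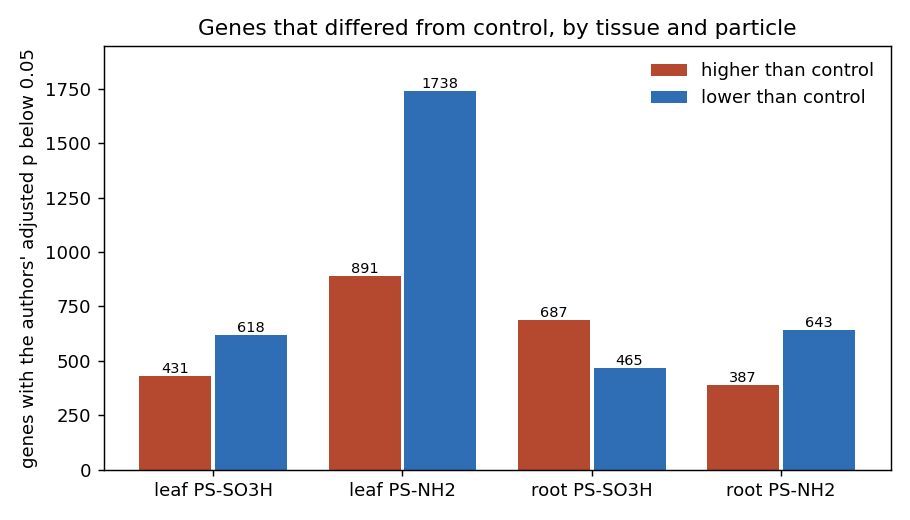
Bars give the number of genes with the authors' adjusted p below 0.05, higher or lower than control, for each tissue and particle; the vertical axis counts genes and starts at 0. Leaf with PS-NH2 has 891 higher and 1738 lower genes, and root with PS-SO3H is the comparison with more higher genes (687) than lower (465).

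The leaf comparison of PS-NH2 with control asked which leaf transcripts differ in seedlings raised with the amino-bearing particle. Of the lists fixed in advance, 21 of 23 salicylic acid, 11 of 15 early immune, 10 of 14 ethylene and 20 of 22 glucosinolate genes fell, and 8 of 23 cold and drought genes rose. Among genes lower than control in the authors' deposited table, WRKY33 (AT2G38470), a transcription factor of pathogen defence, had a log2 fold change of -3.18 ± 0.14 (SE). The jasmonate-responsive defensin gene PDF1.2A (AT5G44420) had -3.77 ± 0.34, and the peptide hormone gene RALFL32 (AT4G14010) had -4.62 ± 0.52. The isocitrate lyase gene ICL (AT3G21720), an enzyme of the glyoxylate cycle, rose from a level of 9.97 to 93.55 (log2 3.23 ± 0.44). The table calls 891 genes higher and 1738 lower among 23480 listed, at the authors' adjusted p below 0.05.

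Of 23 genes of salicylic acid signalling and systemic resistance, 21 fell in leaf with PS-NH2 and 0 rose, with a median log2 fold change of -1.93. This list passed the one-sided Fisher's exact test for lower genes with an adjusted p of 1.69e-20. All 23 fell with p adjusted over the list alone. WRKY70, a regulator between salicylic acid and jasmonate responses, had -1.72 ± 0.16. The transcription factor genes CBP60G and SARD1, which drive salicylic acid synthesis, had -2.13 ± 0.20 and -2.52 ± 0.27. GRX480, a glutaredoxin gene induced by salicylic acid, had -3.58 ± 0.37. PR1, the usual marker of the pathway, went from a level of 914 to 183 (-2.32 ± 0.57, authors' adjusted p = 0.00079). The authors' PS-SO3H table fits PR1 at 1416 in the same control libraries.

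Early immune and wound genes gave 11 of 15 lower, 1 higher (WRKY29) and a median of -1.79 in the same table, or 13 lower and 1 higher adjusted over the list alone. The mitogen-activated protein kinase gene MPK3 had -1.99 ± 0.12 and WRKY40 had -2.74 ± 0.21. Of 22 glucosinolate genes, which make the sulfur-rich defence compounds of this plant family, 20 fell and 0 rose, with the same 20 and 0 counts adjusted over the list alone. MYB51, a regulator of indole glucosinolates, had -2.28 ± 0.17 and the sulfotransferase genes SOT16 and SOT17 had -1.29 ± 0.14 and -1.47 ± 0.16. Of 14 ethylene genes 10 fell and 0 rose (11 and 0 adjusted over the list alone), among them ERF2 at -1.94 ± 0.17 and ERF6 at -2.15 ± 0.19.

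Jasmonate genes moved in both directions in leaf with PS-NH2: 16 of 27 fell, 5 rose and both directions passed the list test. The counts were again 16 and 5 adjusted over the list alone. LOX4 had -2.90 ± 0.16, the regulator MYC2 -1.86 ± 0.12 and the repressor gene JAZ7 -3.17 ± 0.26. The 5 that rose were VSP2, LOX2, AOC2, VSP1 and AOS, of which the vegetative storage protein gene VSP2 had 1.60 ± 0.12. The median of -1.16 lay on the side of the lower genes.

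Cold and drought genes rose in leaf with PS-NH2: 8 of 23 were higher and 1 (RD26) lower, or 9 and 3 adjusted over the list alone. COR15B and KIN2, which encode proteins made in the cold, had 2.26 ± 0.26 and 2.00 ± 0.17. COR27, a cold-induced regulator of the clock, had 1.76 ± 0.19, and the flowering regulator gene CO had 2.14 ± 0.25. Phosphate starvation genes gave 8 of 17 lower and 0 higher (10 and 0 adjusted over the list alone), and glutathione S-transferase genes 12 of 35 lower and 1 higher, GSTF12 (12 and 1 adjusted over the list alone). Flavonoid genes split: 9 of 21 fell, among them CHS, the first enzyme of the branch, at -1.49 ± 0.17. The 5 that rose were UGT79B1, DFR, LDOX, UGT75C1 and 5MAT, late steps that lead to anthocyanins; the counts were 10 and 6 adjusted over the list alone.

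Photosynthesis genes gave 13 of 34 lower and 1 higher (GAPB) in leaf with PS-NH2, with a median of -0.13, and 13 and 2 adjusted over the list alone. The lower ones included the light-harvesting genes LHCB2.1, LHCB2.2 and LHCB3, while the Rubisco gene RBCS1A stood at 0.24 ± 0.12 (authors' adjusted p = 0.24). Clock genes, listed as a marker of harvest time, gave 5 of 12 lower (CCA1, RVE8, LHY, GI and PRR7) and 1 higher (PRR5), and 5 and 1 adjusted over the list alone. Seed storage genes gave 2 of 7 higher, OLEO1 at 1.89 ± 0.57 and CRA1 at 1.68 ± 0.57 (3 adjusted over the list alone), and missed the list test (Fisher's exact adjusted p = 0.0608). Antioxidant enzymes gave 6 of 20 lower and 2 higher, DHAR1 and TAPX (8 and 2 adjusted over the list alone). CAT2, a catalase gene, had -0.49 ± 0.14. The superoxide dismutase genes CSD1 and FSD1 had -0.61 ± 0.17 and -0.32 ± 0.10, and RBOHD, which encodes a superoxide-forming oxidase, had -1.59 ± 0.11. The test for lower genes also passed for heat shock (6 of 18), sulfur limitation (6 of 14), reactive oxygen (4 of 10), auxin (4 of 13) and nitrogen genes (4 of 14). Those counts were 7, 7, 6, 5 and 5 adjusted over the list alone. Cell wall loosening passed for higher genes, with 6 of 19 higher and 4 lower, and the same counts adjusted over the list alone. In all, 20 of the 48 list tests passed here, and 6 of them were lost with calls at adjusted p of at most 0.001 and an absolute log2 fold change of at least 1.

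**Figure D2:**
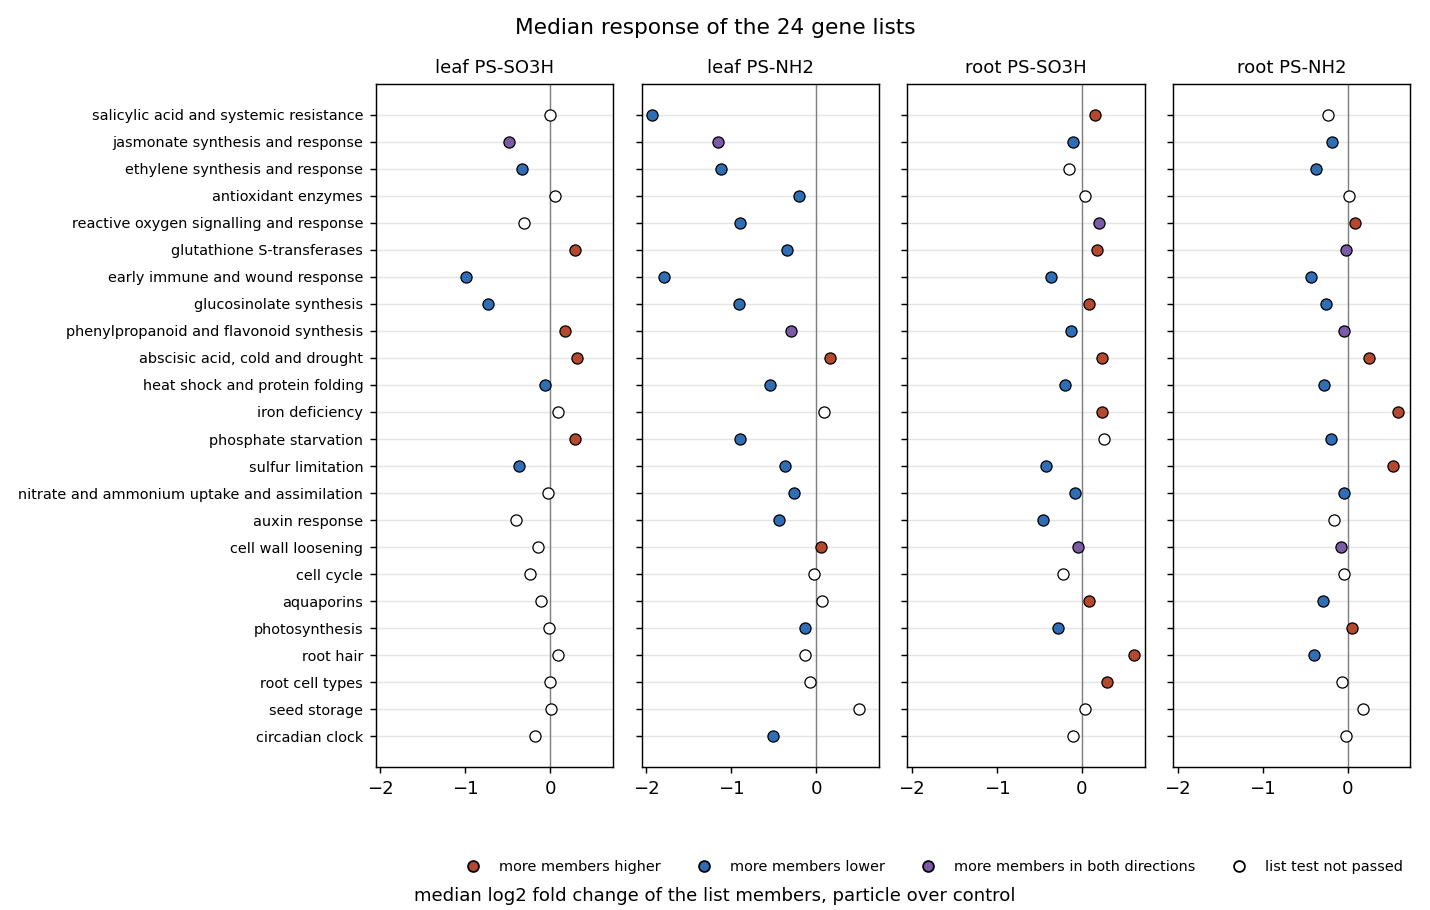
Each point is the median log2 fold change, particle over control, of 1 of the 24 gene lists in the authors' deposited table named above the panel; colour shows in which direction the list had more changed members than other genes by a one-sided Fisher's exact test. The salicylic acid list sits at -1.93 in leaf with PS-NH2 and the sulfur limitation list at 0.54 in root with PS-NH2.

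The leaf comparison of PS-SO3H with control asked the same question of the sulfonated particle. In all, 17 of 22 glucosinolate, 9 of 15 early immune and 7 of 14 sulfur genes fell, jasmonate genes moved in both directions (12 of 27 lower and 4 higher), and 8 of 35 glutathione S-transferase genes rose. ERF109 (AT4G34410), a transcription factor of wounding and redox stress, fell from a level of 243 to 20.28 in the authors' deposited table (log2 -3.58 ± 0.31). UGT79B1 (AT5G54060), an anthocyanin glycosyltransferase gene, rose from 58.41 to 261 (2.16 ± 0.27). The table calls 431 genes higher and 618 lower among 23529 listed.

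Of 22 glucosinolate genes 17 fell and 0 rose in leaf with PS-SO3H, with a median of -0.74 and an adjusted p of 1.21e-21 in the one-sided Fisher's exact test. All 22 fell with p adjusted over the list alone. CYP79F1, which starts the synthesis of methionine-derived glucosinolates, had -1.47 ± 0.13, and CYP81F2, of the indole branch, had -1.79 ± 0.18. Early immune genes gave 9 of 15 lower and 0 higher (9 and 1 adjusted over the list alone), among them WRKY33 at -2.18 ± 0.14 and SZF1 at -2.37 ± 0.16. Jasmonate genes gave 12 of 27 lower and 4 higher (LOX2, AOC2, VSP2 and AOS), and 12 and 5 adjusted over the list alone. Both directions passed, with a median of -0.49. LOX4 had -2.03 ± 0.15 and MYC2 -1.46 ± 0.13, while LOX2, a lipoxygenase gene of jasmonate synthesis, had 1.55 ± 0.16. Sulfur limitation genes gave 7 of 14 lower and 1 higher, BGLU28 (7 and 4 adjusted over the list alone). APR1, which encodes a sulfate-reducing enzyme, had -1.83 ± 0.15. Ethylene genes gave 6 of 14 lower and 1 higher, EBF2 (7 and 1 adjusted over the list alone).

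Glutathione S-transferases, enzymes that conjugate foreign and reactive compounds, gave 8 of 35 higher and 2 lower (GSTF11 and GSTU20) in leaf with PS-SO3H, with the same counts adjusted over the list alone. GSTU24 had 1.43 ± 0.27 and GSTU7 0.91 ± 0.19, and GSTF11 had -1.88 ± 0.22. Outside the lists, the transporter gene DTX1, linked to the export of toxic compounds, had 1.67 ± 0.23. Flavonoid genes gave 5 of 21 higher (UGT79B1, LDOX, DFR, UGT75C1 and 5MAT), or 6 higher and 1 lower adjusted over the list alone. Cold and drought genes gave 5 higher (KIN2, KIN1, RD20, LTI30 and ABI1) and 1 lower (RD26) of 23, or 10 and 4 adjusted over the list alone. Phosphate starvation genes gave 4 of 17 higher (IPS1, AT4, RNS1 and SQD1), or 5 adjusted over the list alone, of which the non-coding RNA gene IPS1 had 1.73 ± 0.18. Heat shock genes gave 3 of 18 lower (HSP70, HSP90.1 and ROF2; 3 adjusted over the list alone), a call that was lost when fold changes were re-centred on the median gene.

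The salicylic acid list did not pass in leaf with PS-SO3H: 2 of 23 rose (PR5 and DLO1), 3 fell (WRKY18, CBP60G and WRKY70) and the median was -0.01. Adjusted over the list alone, 2 rose and 5 fell. The wider ontology term of salicylic acid metabolism in the authors' table, tested after the data were examined, held 36 of 278 genes lower with PS-SO3H (Fisher's exact adjusted p = 3.6e-13) and 127 of 277 with PS-NH2. PR1 stood at 0.75 ± 0.43 (authors' adjusted p = 0.52), and RBOHD fell (-1.13 ± 0.13). Of the photosynthesis, root hair, root cell type and cell cycle lists, 0 members were called in the authors' table, whose unadjusted p was below 0.05 for 2906 genes over the whole table. Their medians lay at percentiles 14.56, 97.29, 47.48 and 0.32 of random lists matched for level, and that of cell cycle genes was -0.24. Auxin genes missed the list test with 1 of 13 lower (5 adjusted over the list alone), but had a median of -0.41 at percentile 0. In all, 11 of the 48 list tests passed, 1 of which was lost at the stricter limits.

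Particles at the same dose were set against each other in leaf through the difference of their log2 fold changes, PS-NH2 minus PS-SO3H. Lower with PS-NH2 than with PS-SO3H were 17 of 23 salicylic acid, 10 of 17 phosphate starvation, 9 of 34 photosynthesis and 8 of 35 glutathione S-transferase genes. RALFL32 differed by -4.61 ± 0.61 (95% interval -5.80 to -3.41), PDF1.2A by -3.93 ± 0.54 CHS by -1.63 ± 0.22 and PR1 by -3.07 ± 0.71 (-4.46 to -1.68). Higher with PS-NH2 were COR27 by 1.62 ± 0.29 and COR15B by 1.56 ± 0.39. The difference was called for 734 genes, 135 higher and 599 lower with PS-NH2, at an adjusted p below 0.05 from a normal approximation on the recovered SEs. In 432 of these the authors' fold changes of the 2 particles, called or not, had opposite signs, which choosing genes by a large difference favours. Genes called against control with both particles in opposite directions numbered 24 in leaf.

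Of 23 salicylic acid genes 17 differed in leaf, each lower with PS-NH2 (21 adjusted over the list alone), with a median difference of -1.86 and an adjusted p of 3.5e-21 in the one-sided Fisher's exact test. Phosphate starvation genes gave 10 of 17 lower, median -1.25 (15 adjusted over the list alone). Photosynthesis genes gave 9 of 34 lower, glutathione S-transferases 8 of 35, and ethylene, flavonoid and jasmonate genes 5 each of 14, 21 and 27. Adjusted over the list alone these were 9, 11, 8, 7 and 5. Early immune genes gave 4 of 15 lower (WRKY33, CYP71A13, NHL10 and WRKY53) and clock genes 3 of 12 (CCA1, LHY and RVE8), or 8 and 4 adjusted over the list alone. Higher with PS-NH2 were 3 of 19 cell wall genes (XTH9, XTH22 and EXPA11), 2 of 18 aquaporins (PIP2;7 and TIP2;1) and 2 of 23 cold genes (COR47 and COR15B), or 4, 2 and 4 adjusted over the list alone. Against the direction of their lists, 1 ethylene and 1 early immune gene were higher and 1 cold gene was lower. Adjusted over the list alone these were 1, 2 and 3. Glucosinolate genes fell with both particles in 17 of 22 cases. In the particle difference 3 of 22 were called lower with PS-NH2 (MYB51, CYP83B1 and SOT16), which missed the list test (Fisher's exact adjusted p = 0.068). Jasmonate genes fell with both particles in 12 of 27 cases and rose with both in 4. Early immune genes fell with both in 7 of 15 cases and rose with both in 0. The same control libraries serve both particles. For genes changed with both, control levels that stand apart cannot be told from an effect of both particles without values per library. Of 12 list tests that passed here, 8 were lost at the stricter limits, those of salicylic acid, phosphate, photosynthesis and clock genes being kept.

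For several genes fixed in advance no difference between the particles was called in leaf. The difference was -0.25 for APX1 (95% interval -0.56 to 0.05), -0.48 for CAT2 (-0.87 to -0.10), 0.06 for RBCS1A (-0.29 to 0.41) and 0.60 for VSP2 (0.20 to 1.01). It was -0.72 for CSD1 (-1.19 to -0.25), -0.17 for FSD1 (-0.47 to 0.14) and -0.46 for RBOHD (-0.80 to -0.13). These intervals are not adjusted for the number of genes tested, and those of CAT2, VSP2, CSD1 and RBOHD leave out 0. A missing call therefore does not show that the particles had the same effect. Both fold changes share the control libraries, which makes the summed SE too large. With a covariance for the shared controls taken out, 1925 genes differed in leaf, among them VSP2, CAT2, CSD1 and RBOHD.

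**Figure D3:**
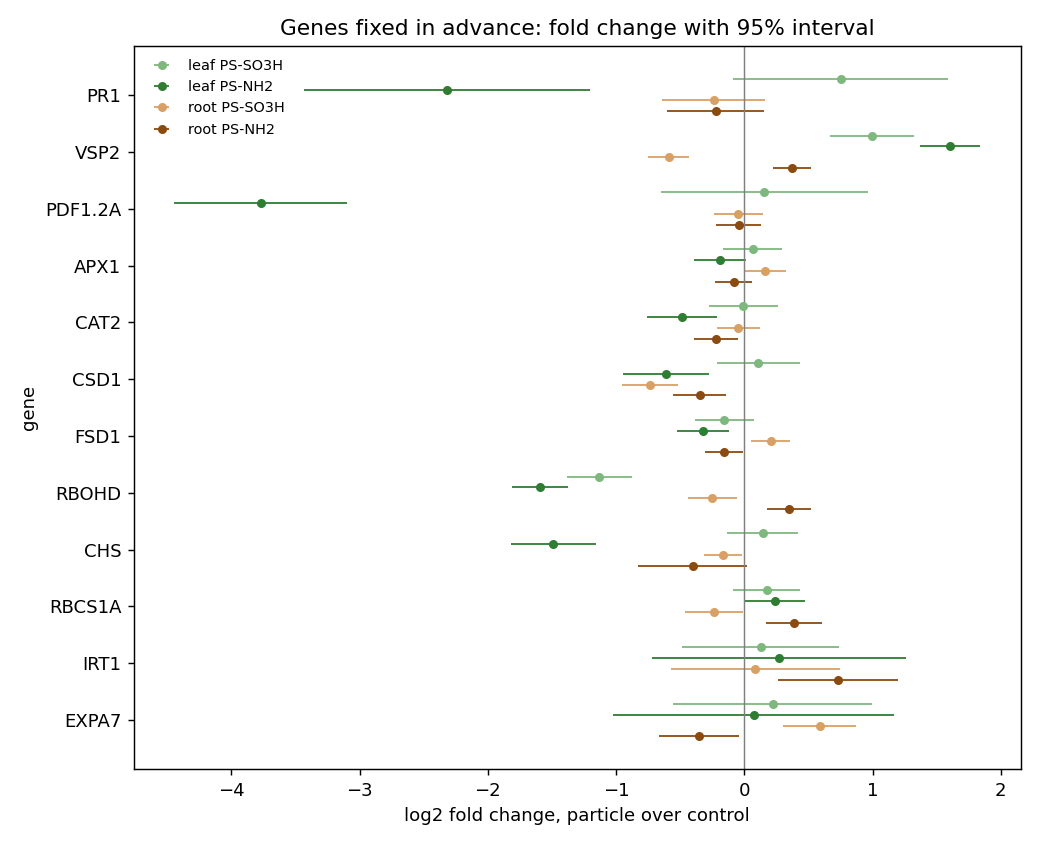
Points give the log2 fold change, particle over control, of the 12 genes fixed in advance in the authors' 4 deposited tables, and lines their 95% intervals from the recovered SEs; colours mark tissue and particle. PR1 and PDF1.2A sit at -2.32 and -3.77 in leaf with PS-NH2, while the intervals of the other 3 comparisons include 0.

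The root comparison of PS-NH2 with control asked which root transcripts differ with the amino-bearing particle. Of sulfur limitation and iron deficiency genes 10 of 14 and 7 of 22 rose, and of glucosinolate and aquaporin genes 8 of 22 and 7 of 18 fell. DFR (AT5G42800), a late flavonoid enzyme gene, rose from a level of 28.59 to 227 in the authors' deposited table (log2 2.99 ± 0.28). AZI1 (AT4G12470), which encodes a lipid transfer protein of systemic immunity, fell from 4105 to 437 (-3.23 ± 0.11). The table calls 387 genes higher and 643 lower among 23839 listed.

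Of 14 sulfur limitation genes 10 rose in root with PS-NH2 and 1 fell, with a median of 0.54 and a Fisher's exact adjusted p of 5.14e-14 (12 and 1 adjusted over the list alone). LSU1 and SDI1, genes induced when sulfur is short, had 1.94 ± 0.17 and 2.08 ± 0.21. The gene that fell was SULTR1;2, a sulfate uptake transporter, at -0.69 ± 0.08. Iron deficiency genes gave 7 of 22 higher and 0 lower, median 0.59 (11 and 0 adjusted over the list alone). CYP82C4 had 1.46 ± 0.14 and FRO2, the root ferric reductase gene, had 1.17 ± 0.12. The iron transporter gene IRT1 stood at 0.73 ± 0.24 (authors' adjusted p = 0.054), and its call was gained when genes below a level of 10 were left out. Flavonoid genes gave 5 of 21 higher (DFR, LDOX, UGT79B1, UGT75C1 and 5MAT) and 3 lower (FLS1, 4CL3 and F3H), or 6 and 4 adjusted over the list alone. Both directions passed, with a median of -0.04. The nitrate transporter gene NRT2.1 had 1.76 ± 0.13.

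Glucosinolate genes gave 8 of 22 lower and 0 higher in root with PS-NH2, with a median of -0.26 (11 and 1 adjusted over the list alone), among them IPMI2 at -0.50 ± 0.09. Aquaporins, which encode water channels, gave 7 of 18 lower and 1 higher, PIP2;5 (11 and 1 adjusted over the list alone). PIP2;3 had -0.77 ± 0.10 and TIP1;1 had -0.64 ± 0.10. Ethylene genes gave 6 of 14 lower and 1 higher, ACS7 (8 and 1 adjusted over the list alone), among them ERF6 at -0.72 ± 0.15. Jasmonate genes gave 7 of 25 lower and 2 higher (VSP2 and VSP1), heat shock genes 6 of 18 lower, and early immune genes 4 of 14 lower (TCH3, WRKY33, CYP71A12 and NHL10). Adjusted over the list alone these lower counts were 9, 8 and 8. Root hair genes gave 3 of 18 lower (PRP1, EXPA18 and RBOHC; 6 adjusted over the list alone) with a median of -0.40. Phosphate starvation genes gave 3 of 17 lower (PHT1;1, PHO1-H1 and PHT1;4) and 1 higher (RNS1), and nitrogen genes 3 of 15 lower (AMT1;2, NIA2 and LBD39) and 2 higher, with 3 and 5 lower adjusted over the list alone.

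Cold and drought genes gave 5 of 23 higher (KIN1, KIN2, P5CS1, COR15A and LTI30) and 2 lower in root with PS-NH2, or 9 and 2 adjusted over the list alone. Cell wall genes passed in both directions with 4 of 19 higher and 5 lower (5 and 5 adjusted over the list alone). Glutathione S-transferases also passed in both, with 3 of 35 higher (GSTU25, GSTF12 and GSTU24) and 6 lower (3 and 7 adjusted over the list alone), although the call for higher members was lost when genes below a level of 10 were left out. Reactive oxygen genes gave 2 of 10 higher (RBOHD and UPOX) and 1 lower (3 and 2 adjusted over the list alone), and RBOHD had 0.35 ± 0.09. Photosynthesis genes gave 3 of 34 higher (LHCB1.3, GAPA and RBCS1A) and 2 lower (RBCS2B and LHCB1.1), median 0.05, and 5 and 2 adjusted over the list alone. In all, 20 of the 48 list tests passed, and 14 of them, those of glucosinolates and aquaporins included, were lost at the stricter limits. PR1 and PDF1.2A stood at fitted levels below 2 in root with either particle.

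The root comparison of PS-SO3H with control asked the same question of the sulfonated particle. Members that rose were 5 of 18 root hair, 4 of 22 iron, 6 of 23 cold and drought and 8 of 35 glutathione S-transferase genes. Those that fell were 8 of 34 photosynthesis, 5 of 14 sulfur, 6 of 15 early immune and 5 of 18 heat shock genes. BIP3 (AT1G09080), a chaperone gene of the endoplasmic reticulum, rose from a level of 8.84 to 128 in the authors' deposited table (log2 3.86 ± 0.35). The peroxidase gene PRX52 (AT5G05340) fell from 201 to 39.62 (-2.34 ± 0.27). The table calls 687 genes higher and 465 lower among 23818 listed.

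Root hair genes gave 5 of 18 higher (COBL9, XTH26, EXPA18, EXPA7 and RSL2) and 0 lower in root with PS-SO3H, with a median of 0.61 and 12 higher adjusted over the list alone. EXPA7, an expansin gene of root hairs, had 0.59 ± 0.14. Root cell type genes gave 3 of 11 higher (NAI2, BGLU23 and CASP5; 6 adjusted over the list alone). Iron deficiency genes gave 4 of 22 higher (OPT3, IMA2, IMA1 and PDR9; 7 adjusted over the list alone), and cold and drought genes 6 of 23 (8 adjusted over the list alone). Glutathione S-transferases gave 8 of 35 higher and 3 lower (GSTF7, GSTF6 and GSTF3), or 12 and 6 adjusted over the list alone. Salicylic acid genes gave 7 of 23 higher and 1 lower, or 8 and 2 adjusted over the list alone. The pathogenesis-related genes PR5 and PR2 had 2.34 ± 0.38 and 1.98 ± 0.38 from levels of 8.90 and 11.8, and FMO1, of systemic resistance, had -1.36 ± 0.35. Aquaporins gave 5 of 18 higher (TIP2;1, PIP1;5, PIP2;7, PIP1;3 and PIP2;4) and 2 lower, or 6 and 4 adjusted over the list alone. Glucosinolate genes gave 6 of 22 higher and 2 lower (MYB51 and CYP81F2), or 7 and 2 adjusted over the list alone.

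Photosynthesis genes gave 8 of 34 lower and 0 higher in root with PS-SO3H, with a median of -0.29 and 17 lower adjusted over the list alone. PORB, of chlorophyll synthesis, had -0.62 ± 0.12 and LHCB1.3 had -0.36 ± 0.08. The median of 59 other leaf-enriched genes in the same comparison was -0.25. Sulfur limitation genes gave 5 of 14 lower (SULTR2;1, SULTR1;2, APR3, APR2 and SULTR4;2) and 0 higher, or 9 and 0 adjusted over the list alone, with SULTR2;1 at -0.95 ± 0.12. Early immune genes gave 6 of 15 lower and 1 higher, NHL10 (6 and 1 adjusted over the list alone). TCH3, a calmodulin-like gene induced by touch, had -1.44 ± 0.13. Heat shock genes gave 5 of 18 lower (HSP70, HSP90.1, HSP101, ROF2 and MBF1C) and 1 higher (BIP3), jasmonate genes 5 of 26 lower (VSP2, JAZ9, JAZ6, JAZ10 and JAZ5) and 1 higher (VSP1), and flavonoid genes 5 of 21 lower (FLS1, 4CL3, F3-PRIME-H, F3H and UGT78D2). Adjusted over the list alone, 6, 8 and 5 of these were lower.

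Cell wall genes passed in both directions in root with PS-SO3H: 5 of 19 rose (XTH15, XTH17, XTH24, EXPA11 and XTH19) and 6 fell, or 6 and 7 adjusted over the list alone. EXPA1 had -0.91 ± 0.10 and XTH17 had 0.97 ± 0.14. Auxin genes gave 3 of 13 lower (GH3.2, GH3.5 and GH3.6) and nitrogen genes 3 of 14 lower (NIR1, AMT1;2 and LBD39), or 5 and 3 adjusted over the list alone. Reactive oxygen genes passed in both directions, with 3 of 10 higher (UPOX, AOX1A and ZAT12) and 2 lower (ZAT10 and ERF109), or 3 and 3 adjusted over the list alone. The call for lower ones was lost when genes below a level of 10 were left out. CSD1 had -0.74 ± 0.11 and APX1 stood at 0.16 ± 0.08 (authors' adjusted p = 0.39). The seed storage and clock lists had 0 members called here, in a table whose unadjusted p was below 0.05 for 2772 genes. In all, 20 of the 48 list tests passed, and 16 of them, those of root hair, photosynthesis and sulfur genes included, were lost at the stricter limits.

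In root the particles differed in 11 of 14 sulfur, 9 of 18 root hair, 8 of 22 glucosinolate and 7 of 18 aquaporin genes. LSU1 was higher with PS-NH2 than with PS-SO3H by 2.27 ± 0.29 on the log2 scale (95% interval 1.70 to 2.83), SDI1 by 2.15 ± 0.35 and the lipid transfer protein gene LTP3 by 2.14 ± 0.19. Lower with PS-NH2 were PRP1, a cell wall protein gene of root hairs, by -2.54 ± 0.39, and the sugar exporter gene SWEET11 by -2.32 ± 0.48. EXPA7 differed by -0.94 ± 0.21 VSP2 by 0.96 ± 0.11, RBOHD by 0.60 ± 0.13, RBCS1A by 0.62 ± 0.16 and FSD1 by -0.36 ± 0.11. The difference was called for 761 genes, 229 higher and 532 lower with PS-NH2. In 591 of them the 2 fold changes, called or not, had opposite signs, which the choice by a large difference favours. Genes called against control with both particles in opposite directions numbered 87 in root.

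Of 14 sulfur limitation genes 11 were higher with PS-NH2 than with PS-SO3H in root, with a median difference of 0.98 and a Fisher's exact adjusted p of 1e-18 (11 adjusted over the list alone). Photosynthesis genes gave 6 of 34 higher, median 0.37 (14 adjusted over the list alone), and flavonoid genes 4 of 21 higher (DFR, UGT75C1, UGT79B1 and LDOX; 5 adjusted over the list alone). Root hair genes gave 9 of 18 lower with a median of -0.90 (14 adjusted over the list alone). In the same comparison the root cell type markers had a median of -0.38 with 2 of 11 lower (NAI2 and CASP4; 6 adjusted over the list alone; Fisher's exact adjusted p = 0.0842), and the photosynthesis list is the marker of green tissue. Glucosinolate genes gave 8 of 22 lower, aquaporins 7 of 18, glutathione S-transferases 7 of 35, salicylic acid genes 5 of 23 (PR2, PR5, DMR6, ALD1 and WRKY70) and ethylene genes 3 of 14. Adjusted over the list alone these were 15, 10, 11, 7 and 4. Nitrogen genes gave 2 of 14 higher (NRT2.1 and NIR1; 2 adjusted over the list alone) with a median of -0.02, on the other side from the test. Cell wall genes passed in both directions, with 5 of 19 higher and 3 lower (5 and 4 adjusted over the list alone). Of 12 list tests that passed here, 9 were lost at the stricter limits, and those of sulfur, root hair and higher cell wall genes were kept.

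No difference between the particles was called in root for APX1 (-0.25, 95% interval -0.46 to -0.03), CAT2 (-0.18, -0.42 to 0.07), CSD1 (0.39, 0.09 to 0.69), CHS (-0.24, -0.68 to 0.21) or IRT1 (0.65, -0.16 to 1.46). The intervals of APX1 and CSD1 leave out 0 but are not adjusted for the number of genes tested. With a covariance for the shared controls taken out of the SE, 2118 genes differed in root, among them APX1 and CSD1.

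Overlap between particles was counted within each tissue. In leaf 154 genes rose and 503 fell with both particles, where independent lists would share 16.5 and 46.4, and 24 changed in opposite directions. In root 130 rose and 120 fell with both, against 11.3 and 12.7 for independent lists, and 87 changed in opposite directions. Across genes, which are not independent replicates, fold changes of the 2 particles correlated with r = 0.495 in leaf, and simulated unchanged groups set against the same controls gave 0.492. Their covariance was 0.0782 in leaf against a simulated 0.0391, and 0.0177 in root against a simulated 0.0222. The root correlation was 0.246, below the simulated 0.499. The simulation drew each fold change with the full recovered SE. Where deposited fold changes are shrunken, as those of low genes look, the simulated covariance may be too large. Without values per library the controls could not be split, so how much of the overlap comes from them was not measured.

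Between leaf and root, 74 genes rose and 72 fell in both tissues with PS-SO3H, where independent lists would share 12.8 and 12.5. With PS-NH2 71 rose and 200 fell in both, against 15 and 47.5. In all 4 comparisons 10 genes rose and 24 fell, against 0.00865 and 0.0271 for independent lists. The 2 comparisons of a tissue share their control libraries, so these independent numbers are too low, and no null with shared controls was run for this count. The 10 include the cold genes KIN1, KIN2 and LTI30 and the nitrate transporter gene NRT2.7. The 24 include the jasmonate repressor genes JAZ5, JAZ6, JAZ9 and JAZ10, the defence genes WRKY33, MYB51 and CYP81F2, and the chaperone genes HSP70, HSP90.1, ROF1 and ROF2.

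Responses of root and leaf were compared through the difference of their log2 fold changes, root minus leaf. With PS-NH2 RBOHD differed by 1.95 ± 0.14 and VSP2 by -1.23 ± 0.14. The difference was called for 1494 genes, 1042 higher and 452 lower in root. With PS-SO3H it was called for 576 genes, 371 higher and 205 lower in root, among them RBOHD at 0.88 ± 0.16. Glucosinolate genes gave 16 of 22 higher in root with PS-SO3H (20 adjusted over the list alone) and 13 of 22 with PS-NH2 (14 adjusted over the list alone). With PS-NH2 17 of 23 salicylic acid genes, 9 of 14 sulfur genes and 11 of 34 photosynthesis genes had higher fold changes in root (20, 9 and 12 adjusted over the list alone). In root with PS-NH2 itself 1 of 23 salicylic acid genes fell (FMO1; 1 adjusted over the list alone) with a median of -0.23, and of the wider ontology term 19 of 268 fell (Fisher's exact adjusted p = 0.0042). Of the salicylic acid genes 2 were higher with PS-SO3H (WRKY70 and PR5) and 1 lower (FMO1), which missed the list test (Fisher's exact adjusted p = 0.143).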

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

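The tests of the 3 explanations for the salicylic acid genes in leaf, and the tests of the root controls, were chosen only after the results were seen. Responses to the same particle that differed between root and leaf, at an adjusted p below 0.05, are set out here because they are differences between groups of samples. Values are root minus leaf log2 fold changes computed from the authors' deposited tables, which were normalized separately for each tissue.

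With PS-SO3H 576 genes differed between the tissues, and 5 lists had members higher in root and 7 lists had members lower in root more often than other genes. BIP3 (3.88), ZAT11 (2.59), ERF109 (2.43), HMT3 (2.34) and JAZ7 (2.26) had higher fold changes in root than in leaf. PRX52 (-2.61), LTP3 (-2.40), DIN2 (-2.21), EXPA16 (-2.16) and IPS1 (-2.05) had lower ones. Of the genes fixed in advance, VSP2 (-1.59) and CSD1 (-0.84) were lower and RBOHD (0.88) was higher.

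With PS-NH2 1494 genes differed, and 12 lists passed for members higher in root and 3 for members lower. RALFL32 (4.42), PDF1.2A (3.73), ERF109 (3.63), GRX480 (3.33) and UMAMIT36 (3.22) had higher fold changes in root than in leaf. ICL (-2.86), ATC (-2.19), COR15B (-2.18), UGT85A3 (-2.18) and FLA13 (-2.18) had lower ones. Of the genes fixed in advance, PR1 (2.1), RBOHD (1.95) and CHS (1.08) were higher and VSP2 (-1.23) was lower. PDF1.2A, PR1, COR15B and UGT85A3 stood at fitted levels below 2 in root, where their fold changes are held near 0, so their values restate the change in leaf.

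Salicylic acid genes were among the tissue differences with PS-NH2: 17 of 23 had higher fold changes in root, and 21 of 23 had fallen in leaf against 1 of 23 in root. The median in root was -0.23, at percentile 0.01 of random lists matched for level. The low count of calls in root therefore does not show that the list was unchanged there. Control libraries rich in immune transcripts would lower these genes with both particles, but 17 of 23 were lower with PS-NH2 than with PS-SO3H, which argues against the controls as the whole cause. The authors' scaling would move genes of all lists alike. In leaf with PS-NH2 the median log2 fold change was 0.0142 over genes at levels of 200 or more and -1.93 for the list. This gap argues against the scaling. The list's median lay at percentile 0 of 10000 random lists matched for level. The list was taken up here because of its fall, so that rank adds no support. Whether 1 of the 2 PS-NH2 libraries stood apart for a reason other than the particle cannot be told apart from an effect of the particle, because 0 columns of the tables hold a value for a single library. A lower salicylic acid response to PS-NH2 in leaf stays a hypothesis, found and tested on the same data.

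Of 34 photosynthesis genes 8 were called lower and 0 higher in root with PS-SO3H, with a median log2 fold change of -0.29. That list call was lost at the stricter limits. Less green tissue in the root PS-SO3H samples may account for this. It predicted, before the value was seen, a fall of other leaf-enriched genes. The median of 59 such genes was -0.25, with 48 of 59 below 0 (7 called lower and 3 higher). These 59 were chosen by their levels alone, so a fall of such genes within root cells predicts the same result. The test cannot tell these 2 explanations apart. More green tissue in the root controls is argued against for the list as a whole by its median of 0.0486 with PS-NH2, set against the same controls. RBCS2B, LHCB1.1 and CA1 fell with both particles (medians of -1.69 with PS-SO3H and -1.66 with PS-NH2), and for these 3 genes high control libraries cannot be told apart from an effect of both particles without values per library. RBCS2B and LHCB1.1 also have near-identical copies, so the way the counting split their reads cannot be left out either. A change of the nuclear photosynthesis genes within root cells stays open and was not tested. Of 88 plastid-encoded genes, 0 were called in root with PS-SO3H, with a median of -0.04.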

How the results depend on the processing

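The tests with a shared-control covariance, an expression floor of 200, re-centred fold changes and controls taken from the tables of 1 particle were added only after the results were seen. No result changed direction under any setting run. Of 268 values of named genes, 182 were run with recomputed adjustment and 182 with re-centring, and all kept their calls; re-centring took only 0.0142 off the leaf PS-NH2 fold changes. With adjusted p at most 0.001 and an absolute log2 fold change of at least 1, which calls fewer genes by construction, 54 named values lost their call. Changed genes then numbered 264 (leaf PS-SO3H), 737 (leaf PS-NH2), 136 (root PS-SO3H) and 151 (root PS-NH2), particle differences 207 in leaf and 172 in root, and tissue differences 169 (PS-SO3H) and 434 (PS-NH2). Genes changed with both particles were 174 in leaf and 29 in root. At that setting 44 list tests passed: 41 of the 95 called tests, with 54 lost, and 3 not called before (cell wall and reactive oxygen genes lower in leaf with PS-SO3H, glucosinolates lower in root with PS-SO3H). Lost in leaf were heat shock with PS-SO3H, and with PS-NH2 antioxidant, reactive oxygen, glutathione S-transferase, auxin, cell wall and clock genes. Kept in root were salicylic acid, early immune, heat shock and iron genes with PS-SO3H, and jasmonate, higher flavonoid, cold and drought, heat shock, iron and sulfur genes with PS-NH2; the other 16 and 14 were lost. The particle differences lost 8 of 12 list calls in leaf and 9 of 12 in root. With adjusted p below 0.05 and the same fold limit, 45 named values lost their call, and the counts in the same order were 340, 976, 208, 220, 456, 296, 305 and 788. At adjusted p of at most 0.01, 7 named values lost their call, and these counts shifted most: 670 (root PS-NH2), 439 and 479 (particle differences in leaf and root), and 347 and 977 (tissue differences with PS-SO3H and PS-NH2). With a covariance for the shared controls taken out of the SE, the particle differences rose by construction to 1925 in leaf (524 higher and 1401 lower) and 2118 in root (692 and 1426), and VSP2, CAT2, CSD1 and RBOHD in leaf and APX1 and CSD1 in root gained a call. That setting takes 0.5 of the variance of each fold change as coming from the control, and in root the observed covariance (0.0177) lay below the simulated one (0.0222), so it may call too many there. At a floor of 10, IRT1 in root with PS-NH2 gained its call, 5 list tests gained a call (seed storage higher in leaf with PS-NH2, nitrogen higher in root with PS-NH2, and auxin higher, iron higher and root cell types lower in the root particle difference) and 2 of the 95 list tests lost theirs (reactive oxygen genes lower in root with PS-SO3H and glutathione S-transferases higher in root with PS-NH2). The cause was not tested. Re-centring ended 1 list call, that of heat shock genes in leaf with PS-SO3H, and the cause was not tested. The tissue check kept its direction throughout: the photosynthesis median went from -6.02 to -6.43 with median scaling and -6.30 with upper-quartile scaling. Root hair genes gave 6.69 and 5.69 with a pseudocount of 0.1 and 5, and 5.97 and 6.10 with the 2 scalings. Root cell types gave 5.95, 4.55, 5.16 and 5.28 in that order; the pseudocount and the scale factor shift these by construction. A shift of 0.1 was counted as a change here, a limit set after these values had been seen and with no replicate spread to set it by; an earlier choice of 0.5 counted fewer of them. No paired analysis was possible because the deposited tables hold one value per group and no value per library. For the same reason alternatives chosen before the data were examined for the tool, normalization, low-count filter, replicate block, samples in the fit, leaving out 1 library, pseudocounts in the tests and correlation-adjusted list tests were not run. Read depth per library is unknown, so what depth limits was not measured.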

Other observations

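The tests of ontology terms and organelle genomes, and the test of harvest time with clock genes, were chosen only after results had been seen; the lists of unfolded protein and detoxification genes were written before their members' values were seen, but after the leading genes of each table had been read.

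Plastid-encoded genes rose in leaf with PS-NH2: 21 of 88 were higher and 2 lower in the authors' deposited table (one-sided Fisher's exact adjusted p = 3.31e-10). The plastid ribosomal protein gene ATCG00330 had a log2 fold change of 1.96 ± 0.40. With PS-SO3H 4 of 88 were higher in leaf and 0 of 88 in root, and with PS-NH2 3 of 87 were higher in root. The median of the plastid-encoded genes in leaf was 0.33 with PS-NH2 and 0.23 with PS-SO3H, and the difference between the particles was not tested. Of genes encoded in mitochondria, 1 of 107 and 2 of 108 were higher in leaf with PS-SO3H and PS-NH2, and 1 of 112 and 2 of 109 in root. The share of organelle transcripts per library was not analysed here.

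Ontology terms named in the authors' deposited tables were tested per direction with a one-sided Fisher's exact test against all listed genes of a table, with Benjamini-Hochberg adjustment over 962 to 968 tests. In leaf with PS-SO3H, 17 of 42 genes of aromatic amino acid family metabolism were higher (adjusted p = 6.97e-17 in the exact test), along with 29 of 238 of toxin metabolism. Lower there were 52 of 210 genes of immune effector process (adjusted p = 1.2e-32 in the exact test), 36 of 278 of salicylic acid metabolism and 27 of 213 of signalling from the endoplasmic reticulum to the nucleus. In leaf with PS-NH2, 30 of 218 genes of developmental cell growth, 19 of 120 of rhythmic process and 24 of 198 of starch metabolism were higher. With PS-NH2 101 of 210 genes of immune effector process, 127 of 277 of salicylic acid metabolism and 75 of 213 of that signalling term were lower in leaf. Immune effector process was also lower in root, with 33 of 210 genes with PS-NH2 and 13 of 210 with PS-SO3H. Of genes of transition metal ion transport in root, 28 of 178 were higher with PS-SO3H and 29 of 177 lower with PS-NH2, and the difference between the particles was not tested. Terms of meristem maintenance (24 of 199) and of phloem or xylem histogenesis (12 of 86) held lower genes in root with PS-SO3H.

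A wider detoxification response in leaf with PS-SO3H was tested as a hypothesis next to the glutathione S-transferases. Of 15 detoxification genes outside the fixed lists, 5 were called higher (CYP81D11, OPR2, UGT74E2, UGT73B4 and UGT75B1), exactly the number set in advance as the minimum (Fisher's exact p = 5.2e-06). UGT74E2 had 1.33 ± 0.31 in the authors' deposited table. These values are consistent with the hypothesis, which stays one, since the list was written after the leading genes, among them DTX1, had been seen. In root 5 of 14 were higher with PS-SO3H and 5 of 15 with PS-NH2. In leaf with PS-NH2 1 was higher (OPR2) and 4 lower (CYP81D8, ABCG40, ABCC3 and NAC102).

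An unfolded protein response in root with PS-SO3H was tested as a hypothesis next to BIP3. Of 15 other genes of that response 1 was called higher, SAR1A at 1.82 ± 0.36 in the authors' deposited table, where at least 5 had been set as the minimum, so the hypothesis failed. BIP1, BIP2, BIP3 and AER were left out of that list because their values had been seen. In leaf with PS-NH2, which no hypothesis had named, 8 of the 15 were lower (Fisher's exact adjusted p = 3.8e-05), among them BZIP60 at -0.80 ± 0.13. In root with PS-NH2 3 were lower (SDF2, ERDJ3B and CNX1).

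Clock genes in leaf with PS-NH2 were divided by their hour of expression, with PRR5, PRR7 and PRR9 in neither set. Those had log2 fold changes of 0.60, -0.98 and -0.83 (authors' adjusted p = 0.022, 0.0016 and 0.38). The 4 dawn genes (CCA1, LHY, RVE1 and RVE8) had a median log2 fold change of -0.94 in the authors' deposited table, and the 5 evening genes (TOC1, ELF4, LUX, BOA and GI) had a median of 0.0516. An hour of harvest that differed from control was taken to move the 2 sets apart, a rule written after results had been seen. That rule need not hold at every hour. With the evening median near 0 and GI at -1.18, a different hour of harvest cannot be told apart from other changes of these genes.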
